A study of Drosophila melanogaster with 3 samples.

How the data were processed

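Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on whole Drosophila melanogaster embryos of both sexes, aged 0 to 24 h. The embryos came from a transgenic line that carries caup, a homeobox transcription factor of the Iroquois complex, fused at its C terminus to GFP, and an antibody against GFP pulled down the fusion protein. Per the labels, chromatin was sonicated and fragments of 200 to 800 bp were kept. The series holds 1 group of 3 biological replicates, numbered as in the labels. Each replicate's regions were called against a control alignment, per the text notes deposited with the files; the control is not analysed here.

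The deposited files are lists of genomic regions, made by the authors for each of 2 genome builds, dm6 and dm3. For each build there is 1 list per replicate, 1 list from the 3 replicates' pooled alignments, and 1 set kept by a test of irreproducible discovery rate (IDR), named optimal in the deposited notes. IDR keeps regions whose rank is reproducible between replicates. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. Each replicate and pooled list holds exactly 30000 regions, so these lists reach deliberately into weak regions and were never treated as peaks in full. The optimal dm6 set is identical to the 6056 pooled regions of highest signal value. The signal value that the authors deposited for each region is their enrichment statistic, never negative, on a scale that is not given; it was used only to describe, rank and filter regions within 1 list. The deposited −log10 q value of each region was compared with the signal value. It was tied at its maximum for 5083, 2277 and 5158 regions of replicates 1, 2 and 3, and its rank correlation with the signal value was at least 0.997, so it was not used to rank. The deposited offset of each region's summit gave the summit position. Read counts are not part of these lists, so the depth of each library is unknown and no value here is scaled to depth. The p column of the lists holds a placeholder and was not used.

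All coordinates are 1-based on dm6. The reference was Drosophila assembly release 6, the same build as dm6, with the Ensembl release 115 gene annotation. It places 17896 genes, of which 13945 are protein-coding, and 23722 distinct transcription start sites (TSSs) on the 6 chromosome arms 2L, 2R, 3L, 3R, 4 and X. No coordinate was converted between builds, and the dm3 lists were used only among themselves.

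With 1 group there was no test between groups. Replicate support was the share of optimal peaks whose summit lay inside a replicate's top regions, taking as many top regions as there are optimal peaks. Shares have Wilson 95% confidence intervals, which cover counting error only. Chance levels came from 1000 random placements of the summits within their own chromosome arms, which do not model mappability. Each summit was put in 1 location class, in the order promoter (within 1 kb of a TSS), coding exon, untranslated exon, intron and intergenic, and compared with the same placements in a two-sided permutation test. Motifs were sought within 100 bp of each summit and in flanking windows centred 500 bp to each side. An exact two-sided sign test (McNemar) compared each summit with 1 of its flanks, chosen by a fixed seed. The tested motifs were the Iroquois palindrome ACANNTGT, 13 other fixed motifs, the 64 palindromes of the same form and all 2080 6-mers with reverse complements joined. For each of 28 gene lists, the share of genes with a summit within 1 kb of a TSS was compared with 10000 random lists of protein-coding genes matched on decile of gene length, in a two-sided permutation test. A 29th list, the tRNA genes, is described without a matched background. P-values were adjusted by Benjamini-Hochberg within each family, at a threshold of 0.05. Genes count as sampled units in these tests, so the p-values speak of this 1 peak set and not of variation between embryos.

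Named genes were fixed by a rule: ara, caup and mirr; the 10 peaks of highest signal value with the nearest TSS; the 10 protein-coding genes with the most summits in the gene body and 5 kb to each side; and from each list up to 4 members with the highest signal value at a summit within 1 kb of a TSS. Of the names written in the lists, 3 found no match in the annotation and are not analysed here. The 29 lists, the motifs, the tests above and the alternatives named next were set before the data were examined; GC-matched windows, 200 bp motif windows, peaks found in all 3 replicates and left-out replicates were set for the palindrome only, among motifs, and were extended to the 13 other motifs after seeing the data. The weak regions as a background for the gene lists, the comparison of top regions between replicates and the further gene groups and tests of the closing section were also added later. The alternatives set beforehand were dm3 in place of dm6, merged peaks, the 3028 peaks of highest signal value, only peaks found in all 3 replicates, each replicate left out in turn, other top-list lengths, 50% reciprocal overlap, other promoter, motif and gene windows, GC-matched control windows, other matching of the gene lists and a 20 kb window at caup. A replicate was left out by keeping the optimal peaks whose summit lay in the top regions of both other replicates. This kept 4435, 4336 and 4220 peaks without replicates 1, 2 and 3. The kept peaks still came from the pooled alignments of all 3 replicates, so this filter is stricter but removes no replicate's data.

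The tests were tried on simulated data. On 6056 randomly placed summits, 0 location classes were called. A motif written into 10% of one set of flanks raised the share of windows with it by 9.21 percentage points, and the exact sign test gave p = 6.5e-44. Of 200 random lists of 15 genes, 3.5% were called at an unadjusted permutation p of 0.05. Of 200 lists of 15 genes with at least 9 occupied members, 96.5% were called at the same unadjusted threshold. These lists were drawn without regard to gene length. The share called was therefore not measured for lists of long genes or after adjustment. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.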

Results

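The binding of caup fused to GFP was mapped across the genome of whole embryos aged 0 to 24 h, in 3 biological replicates of 1 group. Caup is 1 of the 3 homeobox transcription factors of the Iroquois complex, with ara and mirr, known for roles in prepattern and dorsal identity in the notum, wing and eye. The optimal set held 6056 peaks on dm6, with a median width of 420 bp (105 to 916 bp) and widths that sum to 2.06 Mb. Some peaks overlap, and merging them left 5784 regions. Signal values, the authors' enrichment statistic, ran from 209 to 6496 with a median of 333. The depth of the libraries is unknown, since the lists give no read counts. The large arms carried peaks at similar densities: 47.3 per Mb on 2L, 47.1 on 2R, 46.9 on 3L, 43.9 on 3R and 42.8 on X. The X density (95% interval 40.2 to 45.5) lay below that of chromosomes 2 and 3 together (46.1, 44.9 to 47.4), with intervals that overlap. Chromosome 4, the small and mostly heterochromatic chromosome, carried 20 peaks, 14.8 per Mb (9.06 to 22.9).

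The first question was how far the 3 replicates found the same sites. The strongest peaks were found in all of them: each of the 10 peaks of highest signal value lay in the top list of every replicate, and the peak beside Ugalt, which encodes a Golgi UDP-galactose transporter, ranked 1, 1 and 2. Of all optimal peaks, 82.3% (Wilson 95% interval 81.3 to 83.2) had their summit in the top 6056 regions of replicate 1, 82.3% (81.3 to 83.2) in those of replicate 2 and 86.6% (85.8 to 87.5) in those of replicate 3. Random placement gave 1.49%, 1.66% and 1.67%. The optimal set is itself the 6056 regions of highest signal value in the list pooled from these replicates, as kept by the IDR step. High shares were therefore expected from its construction and no test is given. Peaks in the top lists of all 3 replicates numbered 3796, or 62.7% (61.5 to 63.9), against 0.756% by chance, and 37 peaks (0.611%) were in none. A comparison added after the main results leaves the optimal set aside: of the top 6056 regions of 1 replicate, from 72.5% to 76.2% had their summit in the top 6056 of another, over the 6 ordered pairs, against 1.51% to 1.68% at random. Support fell with pooled signal, as it must when peaks near the pooled cut also lie near each replicate's cut. In the fifth of peaks with the highest signal value 96.6% (95.4 to 97.5) were in all 3 top lists, in the groups after it 93.3%, 79.9% and 37.2%, and in the fifth with the lowest 6.36% (5.12 to 7.88). Across the optimal peaks, which are not independent replicates, Spearman's rho of the signal value was 0.639 between replicates 1 and 2, 0.615 between 1 and 3 and 0.721 between 2 and 3. The share in all 3 top lists depends on the length of those lists: it was 91.4% when they were made 2 times as long.

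**Figure D1:**
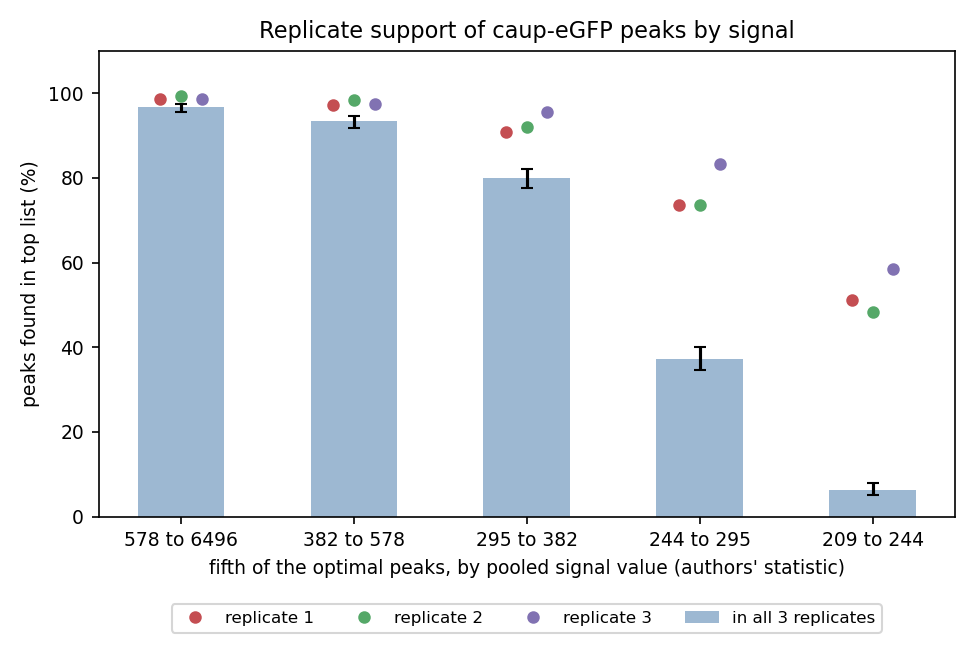
Percent of optimal caup-eGFP peaks whose summit lay in the top 6056 regions of all 3 replicates (bars, with Wilson 95% intervals) and of each replicate (points), for 5 groups of peaks by pooled signal value from highest (left) to lowest (right). The share in all 3 falls from 96.6% to 6.36%.

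The second question was where in the genome caup-eGFP lay. Summits were concentrated at promoters: 3701 of 6056, or 61.1% (Wilson 95% interval 59.9 to 62.3), lay within 1 kb of a TSS, against 23.5% of random placements, 2.60 times as many. Coding exons away from promoters were nearly empty, with 12 summits (0.198%, 0.113 to 0.346) against 10.6% of random placements. Introns held 28.3% against 36.1%, intergenic sequence 8.85% against 25.4% and untranslated exons 1.57% against 4.47%. All 5 classes differed from random placement (adjusted permutation p = 0.002 for each, the smallest that 1000 placements can give). The classes share 1 total and promoters were counted first, so a high promoter share in part forces the others down. The intron share is therefore no separate sign that introns were avoided. Outside promoters introns had the highest ratio to random placement (0.784) and held 1712 of the 2355 summits. The median distance from summit to TSS was 471 bp, against 3222.5 bp for random positions. The promoter share was 71.5% (68.8 to 73.9) in the fifth of highest signal value and 54.1% (51.3 to 56.9) in the lowest. Among the 10000 weakest regions of the pooled list, which lie outside the optimal set, it was 28.1% (27.2 to 29.0).

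**Figure D2:**
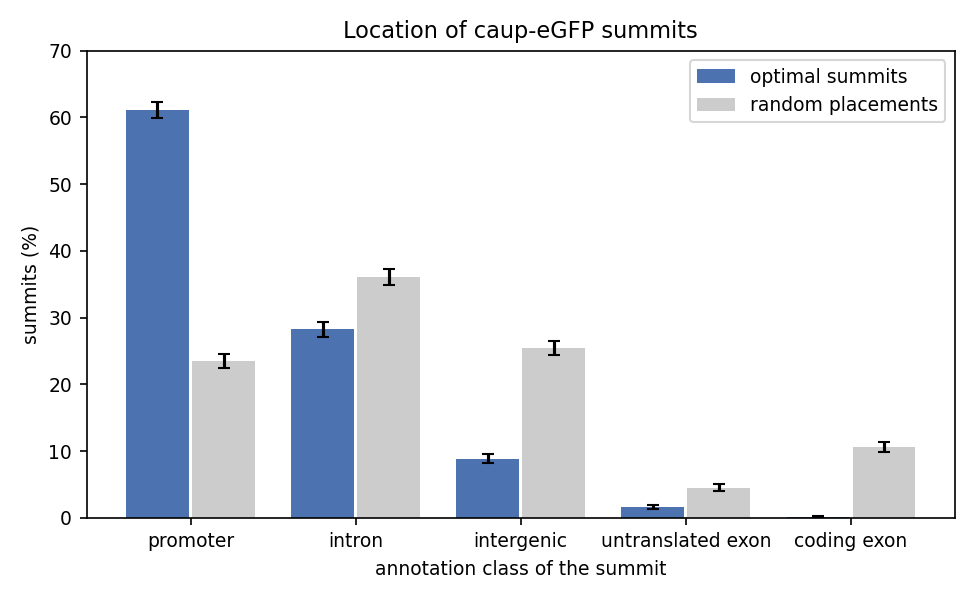
Percent of the 6056 optimal summits in each annotation class (dark bars, Wilson 95% intervals) and of 1000 random placements within chromosome arms (light bars, mean and central 95% of placements). Promoters hold 61.1% of summits against 23.5% at random, coding exons 0.198% against 10.6%.

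The 10 peaks of highest signal value lay at genes of varied function. The highest was on X at 2703664 to 2704102, 26 bp from the TSS of Ugalt (FBgn0024994), with a signal value of 6496. The next was in an intron of CG11050 on 2L at 6612381 to 6612997 (6200), and then a peak on 2L at 480833 to 481342 (5948) inside an intron of ush, a cofactor of GATA factors, whose nearest TSS was that of cbt at 1368 bp. A peak 94 bp from the TSS of CG14100 on 3L reached 5244. An intronic peak of Trl, which encodes the GAGA factor, on 3L at 14759277 to 14759781 reached 4257. The others were nearest to lncRNA:CR44619 (3974), jp (3935), px, a gene of wing vein patterning (3921), mRpL41, a mitochondrial ribosomal protein (3898), and Lk6, a protein kinase (3797). By number of summits in the gene body and 5 kb to each side, ush led with 19, followed by sbb with 18, Eip75B, an ecdysone-induced nuclear receptor, with 16, and CG1677, Tlk and kirre with 15 each. Svil, shn and tara had 14 each and CG14434 had 13. These counts were not adjusted for gene length. Per 100 kb of gene body with 5 kb to each side they ranged from 3.71 at kirre to 51.4 at CG14434, whose gene bodies span 394 kb and 15.3 kb.

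The third question was which groups of genes carried caup-eGFP at their promoters. Genes for the cytoplasmic ribosome stood highest: 79 of 93 ribosomal protein genes (84.9%, Wilson 95% interval 76.3 to 90.8) had a summit within 1 kb of a TSS, against 19.8% in random lists matched on gene length, 4.29 times as many. Housekeeping genes followed, with 12 of 15 (80%, 54.8 to 93.0) against 33.5%. Odorant, gustatory and ionotropic receptor genes, which serve smell and taste, were the only list to pass below its random lists, with 5 of 179 (2.79%, 1.20 to 6.37) against 24.3%. These 3 lists of the 28 passed the test (adjusted permutation p = 0.00187 for each, from an unadjusted 0.0002, the smallest that 10000 lists can give). Over all protein-coding genes 3843 of 13945, or 27.6%, had such a summit, and the share rose from 10.5% in the lowest of 10 classes of gene length to 47.1% in the highest.

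The peaks at ribosomal protein genes were also strong. The strongest promoter summit of each gene stood at a median percentile of 91.9 among optimal peaks by signal value. RpS27 carried the peak ranked 21, 3 bp from its TSS, and RpL7, RpL23A and RpL14 carried those ranked 47, 52 and 55. All 4 were in the top lists of all 3 replicates. Among housekeeping genes the highest signal values were at eEF1alpha1 (1078) and eEF2 (1017), which serve translation elongation, at the glycolytic gene Pgk (943) and at Polr2B (938), a subunit of RNA polymerase II. The housekeeping call was lost with the 3028 peaks of highest signal value alone, though the ratio was nearly the same (46.7% of the genes against 21.1%, ratio 2.22 against 2.39 with all peaks, adjusted permutation p = 0.256). Of the 5 receptor genes with a summit, Or88a, Gr64a, Or9a and Ir60e had the highest values, and in all 4 the summit was nearer to the TSS of another gene: CG12402, CG11594, Neb-cGP and CG13585. The low share of receptor genes is not special to the peaks: the 10000 weakest pooled regions also reached 2.79% of them, against 12.0% in random lists (adjusted permutation p = 0.0056).

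Lists of developmental regulators and tissue markers did not pass the test in either direction. For the heat shock genes, 7 of 11 had a promoter summit (63.6% against 24.2%, adjusted permutation p = 0.0756), with signal values of 3241 at Hsp83, 1257 at Hsp27, 645 at Hsp26 and 354 at CG4456. That last summit lies nearer to the TSS of Hsp22 (432 against 634 bp), so 1 summit supplies 2 of the 7 genes. For the EGF receptor pathway the count was 9 of 13 (69.2% against 43.4%, adjusted permutation p = 0.292), with the ligand genes spi (1049) and Krn (568) and the antagonist genes sty (692) and aos (552) highest. Glial markers had 6 of 10, among them moody (1927), Gs2 (914), loco (581) and pnt (484). The Notch pathway had 7 of 15, with numb (991), neur (626), E(spl)m3-HLH (623) and kuz (451) highest, and the BMP pathway 6 of 14, with brk (712), Mad (561), Dad (283) and tkv (252). The summit counted for kuz was nearer to the TSS of B4 (63 against 874 bp). The BMP count was 2 of 14 with only the peaks in the top lists of both replicates 2 and 3, below the mean of the random lists. It was also 2 of 14, and below that mean, with only the peaks found in all 3 replicates.

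Regulators of the notum and wing, where Iroquois genes are known to act, had 6 of 18 (33.3% against 44.5%, adjusted permutation p = 0.669): brk, Dll (561), ush (359) and pnr (304) had the highest values. Within 5 kb of a TSS the count was again 6 of 18 (33.3% against 59.0%, adjusted permutation p = 0.255). In the gene body plus 5 kb it was 10 of 18 (55.6% against 70.6%, adjusted permutation p = 0.561). The samples were whole embryos, not notum, wing or eye tissue, and summits beyond these windows were not counted. Low counts in these lists therefore do not speak of binding in those tissues or at more distant sites. Eye patterning genes had 4 of 12, namely dac (329), pnr, so (276) and wg (274). Muscle identity genes had 4 of 15, namely org-1 (793), Poxm (499), Mef2 (349.7) and tup (252). Mesoderm and heart regulators had 2 of 15, tin (872) and pnr. Of the segmentation lists, gap and terminal genes had 2 of 10 (hb, 381, and cad, 297), pair-rule genes 1 of 9 (hry, 415) and segment polarity genes 4 of 13 (nkd, 417, ci, 297, wg and smo, 231), the summits of ci and smo being nearer to the TSSs of asRNA:CR43957 and CG17078. Homeotic genes had 1 of 8, Dfd, at a signal value of 225 (12.5% against 46.5%, adjusted permutation p = 0.292).

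The remaining lists of neural genes and of tissue markers all lay below the mean of their random lists without passing the test. Neurogenesis genes had 3 of 16 (elav, 2087, hb, and pros, 219) and neuron markers 3 of 13 (elav, Syx1A, 306, and fne, 255). Contractile muscle markers had 2 of 13 (sls, 609, and Tm1, 311), hemocyte markers 2 of 13 (ush and drpr, 247), fat body markers 1 of 9 (Adh, 383) and tracheal markers 2 of 11 (trh, 827, and bnl, 394). Gut markers had 4 of 11, led by fkh (2372) and Hnf4 (716), epidermal markers 1 of 12 (sn, 339) and germline markers 2 of 10 (gcl, 497, at a summit nearer to CG14767, and vas, 271). Adjusted permutation p-values of these 9 lists ran from 0.292 to 1. When peaks had to lie in the top lists of 2 given replicates, homeotic genes fell to 0 of 8 for every choice of 2. The small counts of the gap and terminal, pair-rule, hemocyte, fat body and germline lists fell by 1 gene for at least 1 choice. The strongest promoter summits of cad and drpr lay outside the top list of replicate 3 only (ranks 7133 and 7071). That of hry lay outside the list of replicate 2 only (12244), and those of Adh and vas outside that of replicate 1 only (6156 and 7229). No single replicate accounts for all these falls. None of the 11 eggshell and yolk genes and none of the 4 achaete-scute genes, the proneural genes, had a promoter summit; these shares of 0 have Wilson upper limits of 25.9% and 49.0%. Of 290 tRNA genes, 37 (12.8%, 9.40 to 17.1) had a summit within 1 kb, the strongest beside tRNA:Tyr-GTA-1-7 and tRNA:Tyr-GTA-1-8 (1839, shared), tRNA:Val-TAC-1-1 (1216) and tRNA:Phe-GAA-1-2 (1157); the summits of these last 2 were nearer to the TSSs of lama and RpL17.

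**Figure D3:**
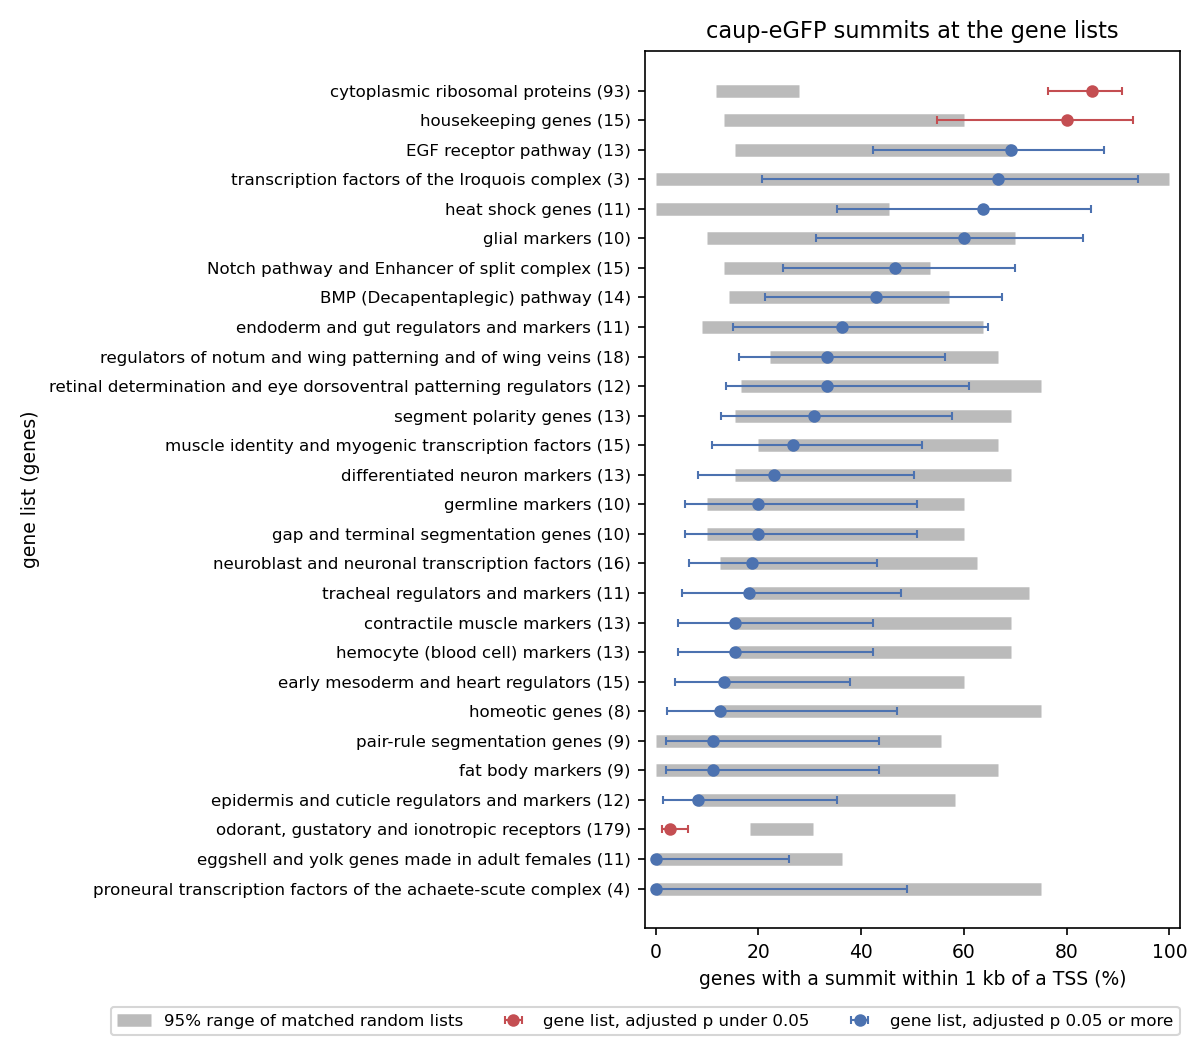
Percent of the genes of each list (number of genes in brackets) with an optimal summit within 1 kb of a TSS (points, Wilson 95% intervals) and the central 95% of 10000 random lists matched on gene length (grey bars). Ribosomal protein genes (84.9%) and housekeeping genes (80%) lie above their random lists and chemoreceptor genes (2.79%) below.

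The fourth question was what lay at the tagged gene and its neighbours. Caup (FBgn0015919, 3L at 12609631 to 12621798, plus strand) had a summit 8 bp from its TSS with a signal value of 312, at the percentile 44.7 of optimal peaks. A stronger peak lay in intergenic sequence 3169 bp upstream, at 12606365 to 12606694 (591). Its pooled summit lay in a region of replicates 2 and 3 (ranks 723 and 1381) and in none of replicate 1, whose nearest region began 13 bp away. Ara (FBgn0015904, 3L at 12580672 to 12596018) had no summit within 1 kb of a TSS and 2 intronic peaks, the stronger at 378. Mirr (FBgn0014343, 3L at 12693639 to 12710249) had 2 promoter summits, the stronger 6 bp from the TSS (308), and 5 peaks in the gene body and 5 kb to each side. As a list, the Iroquois complex had 2 of 3 genes with a promoter summit (adjusted permutation p = 0.922). The strongest peak between caup and mirr, singled out after its value was seen, lay 240 bp from the TSS of lncRNA:CR43431 at 12653200 to 12653445 (714). Within 50 kb of caup there were 10 optimal peaks, against a median of 6 over windows centred on protein-coding genes. This put caup at the percentile 85.0 with ties counted, and 79.9% of windows held fewer. With the 3028 peaks of highest signal value alone there were 3 at caup, equal to the median. The percentile was then 60.5 with ties counted, and 45.7% of windows held fewer.

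**Figure D4:**
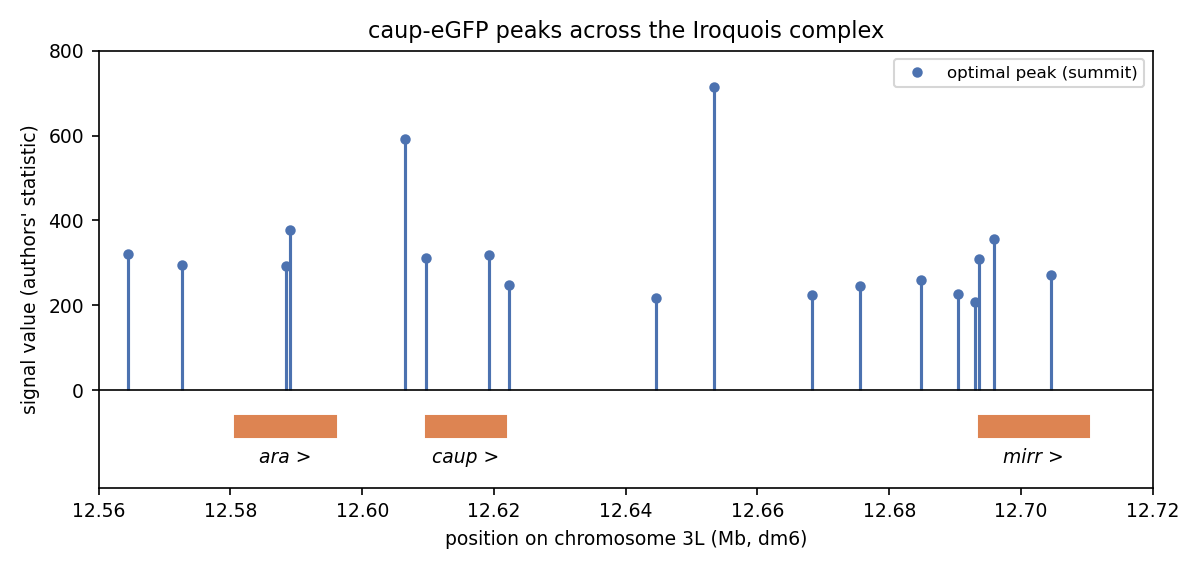
Signal value (the authors' statistic) of each optimal caup-eGFP peak at its summit along chromosome 3L (dm6, Mb), with the gene bodies of ara, caup and mirr as boxes and > for the plus strand. The peak upstream of caup (591) and the peak at lncRNA:CR43431 between caup and mirr (714) are the highest shown.

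The last question was which sequences lay under the summits. The palindrome ACANNTGT, known as a binding sequence of Iroquois proteins, was within 100 bp of 696 summits, or 11.5% (Wilson 95% interval 10.7 to 12.3), against 8.99% of flanking windows, a ratio of 1.28 (exact sign test, adjusted p = 2.28e-06). Its share was 11.4% in the fifth of peaks with the highest signal value and 11.1% in the lowest. Among the 64 palindromes of the same form it ranked 14 by ratio; CAGNNCTG ranked 1 (2.05), TGTNNACA 2 (1.65) and TAANNTTA 3 (1.59). Other spacings of the same ends had ratios of 1.56 (1 base between them), 1.24 (3 bases), 1.47 (4 bases) and 0.992 (none). The form with 1 base includes ACACTGT, which holds ACACTG, a sequence at 18.3% of summits against 7.22% of flanks. The ratio of 1.56 was not separated from that sequence. With 3 and 4 bases an excess was also seen, so it was not confined to a spacer of 2 bases. The summits were poorer in G and C than their flanks, with a median of 37.8% against 42.8%.

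Sequences of housekeeping core promoters had far higher ratios. TATCGATA, the DNA replication-related element, was at 3.62% of summits against 0.636% of flanks, 5.69 times as many (exact sign test, adjusted p = 2.98e-31), and GGTCACAC, part of the core promoter sequence Ohler 1, at 2.81% against 0.627%, 4.47 times as many (adjusted p = 7.34e-25). TATAAA (ratio 1.41), GATAAG (1.31), TAATTA (1.20), CATATG (1.14) and CAGCTG (1.12) were also more frequent at summits, though the call was lost or reversed in 7 of 9 alternatives for CAGCTG, 5 for CATATG and 3 for TAATTA. CACACACA (0.748) and CACATG (0.880) were less frequent, and CACATG lost or reversed its call in 7 of 9. Over all summits ACATGT, GAGAG, CAGGTA and TGACAG did not differ past the threshold. Some of these calls depend on the control windows. The GC-matched windows were drawn on the same arm, outside every pooled region. Against GC-matched windows CACACACA (1.61) and CACATG (1.17) were more frequent at summits, TAATTA was no longer so (0.94) and GAGAG was (1.36), as it also was within 200 bp of the summits (1.11). Away from promoters, at the 2355 summits over 1 kb from a TSS, 2 of the 13 motifs were more frequent in place of 7. TATCGATA lost its call there, at 10 summits (0.425%) and a ratio of 2 (exact sign test, adjusted p = 0.311), and GGTCACAC had a ratio of 1. At the 3701 promoter summits TGACAG was more frequent than in flanks (7.21% against 5.53%, ratio 1.31, exact sign test, adjusted p = 0.000251). CAGGTA was less frequent there (ratio 0.748, exact sign test, adjusted p = 0.0142), and CATATG and CACATG did not pass. Of all 2080 6-mers, 497 were more and 795 less frequent at summits. The highest were ACACTG, with a log2 ratio of 1.34 (18.3% of summits against 7.22% of flanks), CGATAG (1.26), AGTGTA (1.11), ACAGTG (1.01) and CGCTAG (0.96).

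**Figure D5:**
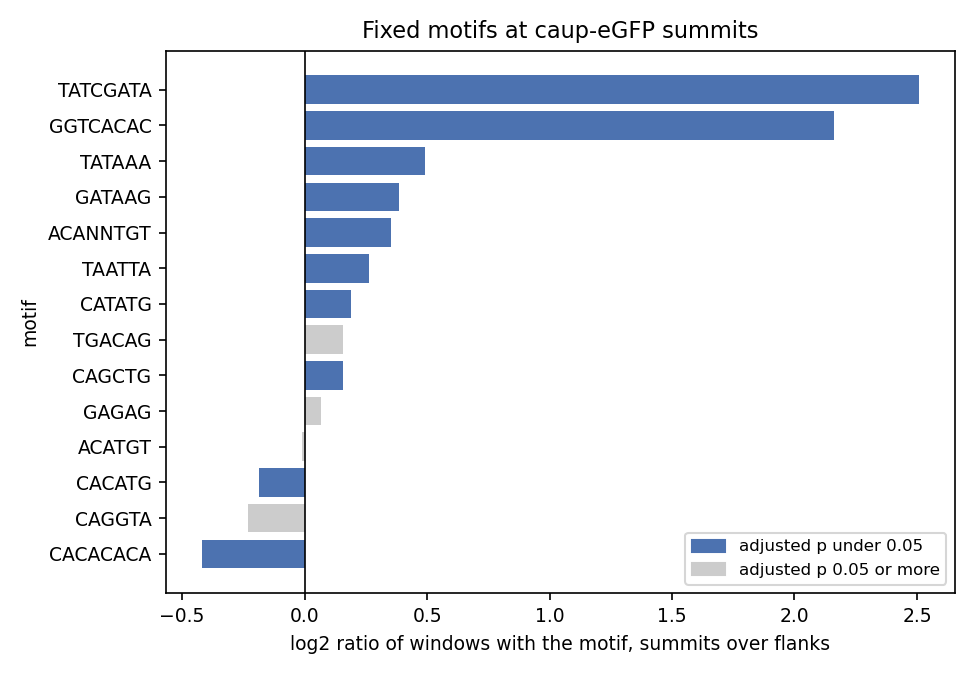
Log2 ratio of the share of windows holding each fixed motif at the 6056 optimal summits over that in flanking windows. Dark bars passed the exact sign test (adjusted p under 0.05), and TATCGATA (2.51) and GGTCACAC (2.16) have the highest ratios.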

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

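The dm3 lists, which serve here only as an alternative build, hold regions outside the 6 chromosome arms, on sequence of the heterochromatin or without a place in the assembly. The count was 12 in the pooled list and 8, 37 and 21 in the lists of replicates 1, 2 and 3, each above the 3 that a count of 0 allows. The dm6 lists hold 0 such regions. No explanation was tested.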

How the results depend on the processing

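The direction and the call of the promoter share, the excess of ACANNTGT at summits, and the calls for ribosomal protein and chemoreceptor genes held under every alternative that was set for them before the data were examined. The promoter share ran from 50.8% with a 500 bp window to 72.4% with a 2 kb window, and the ACANNTGT ratio from 1.25 to 1.63. Of 59 alternatives for the main results, 43 stayed within their limits. The number of peaks was 3028 with a stricter threshold on signal value and 3796 when required in all 3 replicates, both fewer by construction. The share of peaks in all 3 top lists was 91.4% with lists 2 times as long, 32.6% with lists of 0.5 times the length, 43.8% with 50% reciprocal overlap and 61.3% on dm3. With 1 replicate left out it ran from 69.7% to 73.2%, since fewer lists must then hold the peak. The mean share of top regions found in another replicate was 74.1%, but 70.8% with lists 2 times as long, an alternative chosen after seeing the data. Of the 13 fixed motifs, 7 were more frequent at summits, but 2 at summits over 1 kb from a TSS and 4 among the 3028 peaks of highest signal value, both with fewer summits tested; TATCGATA (ratio 2) and GGTCACAC (1) lost their calls over 1 kb from a TSS. CAGCTG turned from 1.12 to 0.887 at summits over 1 kb from a TSS (exact sign test, adjusted p = 0.311), and the cause was not tested. Further alternatives for these 13 motifs were chosen after seeing the data. Of 9 in all, CAGCTG and CACATG lost or reversed their call in 7, CATATG in 5 and TAATTA in 3. Against GC-matched windows CACACACA turned from 0.748 to 1.61, CACATG from 0.880 to 1.17 and TAATTA from 1.20 to 0.94; the cause was not tested. GAGAG passed there (1.36), within 200 bp (1.11) and without replicate 2 (1.09), and CAGGTA without replicate 3 (0.868). The lists above their random lists were 2, but 1 among those 3028 peaks, where the housekeeping genes had 46.7% occupied against 21.1% at random (ratio 2.22, against 2.39 with all peaks) and dropped out, and 0 with the 10000 weakest pooled regions in place of the peaks, an alternative chosen after seeing the data, whose regions lie outside the optimal peaks, and under which the chemoreceptor genes stayed below (2.79% against 12.0%). The percentile of caup by peaks nearby, with ties counted, was 85.0, but 79.3 within 20 kb and 60.5 with those 3028 peaks. The cause was not tested. Among single motifs, lists and location classes, 361 of 397 alternatives kept the call, 25 lost it, 7 gained it and 4 reversed. Heat shock genes passed within 5 kb of a TSS (90.9%) and in the gene body plus 5 kb (100%), where housekeeping genes no longer did (93.3%), and the EGF receptor pathway passed without matching on gene length (69.2%). Several heat shock genes lie close together on 3L, such as CG4456 (start 9372722), Hsp26 (9376418) and Hsp27 (9384063). In these wide windows 1 summit can serve more than 1 of them, which the random lists do not model, so these 2 passes are weak. Ranking by the q value gave no separate value, because of its ties. Depth is unknown, so its effect on weak peaks could not be measured.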

Other observations

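The tests of weak regions at ribosomal protein genes, of GC content alone and of ribosomal protein genes without divergent promoters were chosen after their results had been seen; the gene groups below were chosen after the main results but before their own values were known. Among further groups, 32 of 73 mitochondrial ribosomal protein genes (43.8%, Wilson 95% interval 33.0 to 55.2) had a promoter summit, against 16.0% in lists matched on gene length (adjusted permutation p = 0.0004 over 6 groups). Proteasome subunit genes had 10 of 48 (20.8% against 20.6%, adjusted permutation p = 1). Cuticle and odorant-binding protein genes were low: 2 of 70 Cpr cuticle protein genes (2.86% against 20.4%, adjusted permutation p = 0.0004) and 1 of 51 odorant-binding protein genes (1.96% against 16.0%, adjusted permutation p = 0.0039). None of 16 Jonah protease genes had one (random 14.6%, adjusted permutation p = 0.174). Of 3261 non-coding RNA genes, 448 (13.7%) had a summit within 1 kb.

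At summits nearest a ribosomal protein TSS, TATCGATA, GGTCACAC and CGATAG were more frequent than at other promoter summits, and TATAAA was less so. CGATAG was at 40% against 13.4% (Fisher's exact test, adjusted p = 1.78e-08). TATCGATA was at 21 of these 80 summits (26.3%, Wilson 95% interval 17.9 to 36.8) against 5.19% of the 3621 other promoter summits (Fisher's exact test, adjusted p = 7.21e-09 over 6 motifs). GGTCACAC was at 13.8% against 4.23% (Fisher's exact test, adjusted p = 0.00136) and TATAAA at 17.5% against 30.6% (adjusted p = 0.0199). ACACTG, the leading 6-mer, was at 23.8% against 19.3% (Fisher's exact test, adjusted p = 0.318), and 9.12% of the 1108 summits with ACACTG also held GGTCACAC.

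The first pattern followed up is the set of summits at ribosomal protein promoters, within the general promoter share. An equal preference of all called regions for promoters in general is argued against by the 10000 weakest pooled regions, whose promoter share was 28.1%. For ribosomal protein promoters such a preference cannot be told apart from binding: the weakest regions reached 15.1% of these genes (random 11.2%), but they lie outside the optimal peaks and 79 of the 93 genes already hold one. A background that also makes strong regions at promoters is excluded by neither value. Reach to a neighbouring promoter is argued against, since 82.8% of the genes were themselves the nearest to a summit (random 12.3%), and of the 54 genes without a divergent TSS within 500 bp 83.3% carried one (random 12.9%, permutation p = 0.0002, the smallest that 10000 lists can give). Binding through the Iroquois palindrome was tested as a biological hypothesis and went the other way: ACANNTGT was at 3.75% of these summits (1.28 to 10.5) against 10.9% of other promoter summits (Fisher's exact p = 0.0427, adjusted 0.0513). A draw of open, highly transcribed promoters on any GFP pull-down stays open, since neither a control pull-down nor expression was analysed here.

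The preference was not seen in every group of basic cell machinery tested. Of mitochondrial ribosomal protein genes 43.8% carried a summit, above their random lists, but of proteasome genes 20.8% did, against 20.6% at random. What had been written beforehand asked for both groups or neither, so how far the preference reaches stays open. Divergent promoters are a candidate part of this preference. Of 4105 genes with a TSS of the opposite strand within 500 bp, 43.8% carried a summit against 27.4% at random, and 25.4% against 19.9% when only the gene with the nearest TSS was counted (permutation p = 0.0002 for both).

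The second pattern is the excess of ACANNTGT at summits. An equal share at all called regions is argued against, since 8.63% of the 10000 weakest summits held it, against 11.5% of optimal summits. The weakest summits had a GC content near that of flanks (medians 42.3% and 42.8%, against 37.8% at optimal summits). That comparison therefore cannot tell binding from composition. GC content alone is argued against, since summits held the palindrome 1.63 times as often as GC-matched windows. Those windows were drawn outside every pooled region. The flanks, though richer in G and C, also held it more often (8.99%) than those windows (7.05%), so part of this excess is not particular to summits. Shuffling each summit window with its dinucleotides kept left 1.69 times as many windows with ACANNTGT in the real sequence as in the mean of 100 shuffles, above all of them. The flanks showed nearly the same excess, however: over 20 shuffles the ratio was 1.67 at summits (1.56 to 1.79 over shuffles), 1.51 in left flanks and 1.61 in right flanks, so a change of composition from flank to summit cannot be told apart from binding at this sequence. Spacers of 1 and 4 bases had higher ratios to flanks (1.56 and 1.47) than the spacer of 2. The form with 1 base includes ACACTGT, which holds ACACTG, itself more frequent at summits. The ratio of 1.56 therefore cannot tell an effect of spacing from that sequence. The rank of 14 among 64 palindromes met what had been written for base composition beforehand, and composition beyond GC content stays a candidate explanation.

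The third pattern is the density of regions around caup. Outside the optimal set, the regions within 50 kb numbered 36, 38 and 40 in replicates 1, 2 and 3, against medians of 21, 20 and 19. With ties counted, the percentiles were 93.7, 97.2 and 97.9. An extra copy of the locus in the tagged line may raise such counts. The bound written beforehand was the percentile 95 in all 3 replicates, and replicate 1 missed it at 93.7, so this cannot be told apart from other causes. A general excess at developmental loci also stays open: 69 genes of the segmentation, homeotic, muscle identity and notum and wing lists had median percentiles of 56.3, 54.3 and 68.4, and 6, 4 and 3 of them reached that of caup.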
